A study of Mus musculus with 6 samples.

How the data were processed

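Total RNA of jejunal epithelial cell preparations was hybridised to Affymetrix mouse gene arrays, 250 ng per array, per the labels' protocols. The values deposited by the authors are on the log2 scale, and the submitters' processing notes name RMA (robust multi-array averaging: background correction, quantile normalization and summary of probes to 1 value per row) and Partek 6.5. Settings of these steps are not given in the sources used here. RMA leaves all arrays with nearly the same distribution, so a change in total RNA per cell cannot show, and signals near the lower end of the scale are compressed. The table held 35399 rows with values from 2.41 to 13.5 and no missing value. Each of its 6 columns was mapped to 1 sample, and samples were grouped by the sample titles into 3 control and 3 transgenic arrays. The series text calls them animals, so each array was treated as a biological replicate.

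Rows were named through the platform annotation: 21789 rows had 1 gene symbol, 1621 several and 11989 none. Only rows with 1 symbol were named, 21698 of them were found in a RefSeq gene table of assembly GRCm38.p6 by Entrez ID, and none changed its symbol. That table was used for names and chromosomes only, and coordinates were not used here. For the 999 genes with more than 1 row the row with the highest mean over all arrays was kept, which left 19938 genes, with no filter on dim genes.

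Differences, transgenic minus control, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with Benjamini-Hochberg adjustment over all genes, and a gene passed at an adjusted p under 0.05. All adjusted p-values of single genes come from this test unless stated, and ± is an SD over 3 arrays. A count of genes differing by at least 1.5-fold was taken among those that passed. The 40 gene lists, chosen from general knowledge of the intestine, stress responses and Musashi biology, were tested with camera (inter-gene correlation preset to 0.01), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Members were also counted with adjustment over the list alone. In counts of members, rose, fell, higher and lower mean that the member passed. A smaller count with an array left out is a loss of calls and does not show a lost or reversed difference. Several genes belong to more than 1 list, such as Olfm4, Ascl2, Sesn2 and Atf3. Genes were named by a rule: Msi1 and Msi2, the 14 largest rises and the 14 largest falls among genes that passed with no overlap between groups, and up to 4 members per list with the smallest p plus members whose absence a group sentence would hide, with predicted genes and small RNAs passed over. The tests, samples, lists, naming rule and alternatives, except where stated, were fixed before the data were examined.

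The gene test and the list test were tested on simulated data with 200 changed genes among 19938. At 1.5-, 2-, 4- and 8-fold the gene test recovered 28%, 72%, 86% and 98% of the changed genes, and 3 of its 145 calls were unchanged genes. Each gene was drawn independently with the same SD on all arrays, and no array stood apart. These rates therefore need not hold for the real arrays. The list test called 5 of 5 shifted lists and 0 of 35 others, with genes simulated as independent.

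The alternatives were quantile normalization, equal array medians, removal of the dimmest 40% of genes, a block on the replicate number of the titles or on the number in the sample descriptions, eBayes with trend and robust settings, array weights, the mean of a gene's rows, leaving out each array in turn, an adjusted p under 0.1, all rows tested, and for lists camera with an estimated correlation, camera on ranks and fry. Leaving out transgenic replicate 1 together with control replicate 1, and camera with an estimated correlation without transgenic replicate 1, were added after the data were seen.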

Results

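RNA from total epithelial cell preparations of mouse jejunum, the middle part of the small intestine, was measured on whole-transcript gene arrays. Of the arrays, 3 came from control animals with R26-M2rtTA, a doxycycline-dependent activator of transcription, and 3 from animals that also carried a Musashi transgene driven by that activator. All animals had received doxycycline for 24 h, so the comparison shows the state of the epithelium after 24 h of transgene induction. Musashi proteins bind RNA and are known for their role in stem and progenitor cells. The values were log2 signals, with array medians from 6.27 to 6.34 over 35399 rows, and 19938 named genes were tested. The number of arrays, 3 per group, limits the precision of each difference.

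The induced gene was Msi1. Its signal (row 10524684) was 6.94 ± 0.09 in the control arrays and 12.60 ± 0.09 in the transgenic arrays (mean log2 ± SD, n = 3 each), a rise of 5.66 (SE 0.0894, limma adjusted p = 1.34e-05) or 50.5-fold, and all 3 transgenic arrays lay above 12.5. Msi2 (row 10389680) was 8.64 ± 0.06 in the controls and 8.22 ± 0.30 in the transgenic arrays, a difference of -0.42 that did not pass (SE 0.16, limma adjusted p = 0.168). Without transgenic replicate 1 the Msi2 difference was -0.60 with an adjusted p of 0.0011. The series text names Msi1 as the transgene, and the genotype label of the transgenic samples names MSI2. The Msi1 signal separated the groups in the way that the series text describes, and no array of the group labelled transgenic had a higher Msi2 signal than the controls. An exact two-sided permutation test of 3 against 3 arrays cannot go below p = 0.1, which was its value for both genes.

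**Figure D1:**
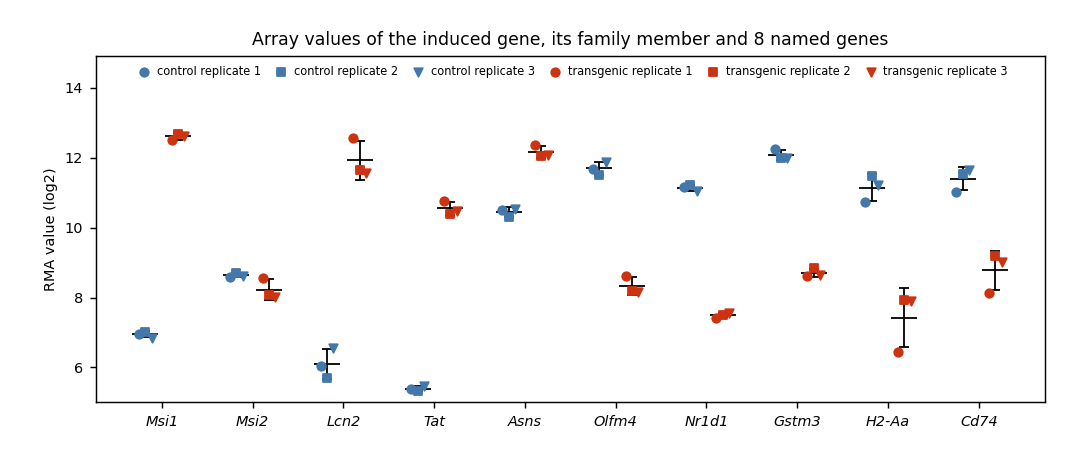
Log2 RMA value (vertical axis) of 10 genes (horizontal axis) on each array, with control arrays in blue and transgenic arrays in red, a marker shape per replicate number, and the group mean with SD in black (n = 3). Msi1 lay at 12.60 in the transgenic group and 6.94 in the control group, and for Msi1, Tat, Nr1d1 and Gstm3 the difference was many times the spread between arrays.

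After 24 h of doxycycline in both groups the transgenic epithelium differed widely from the control epithelium. No array came from an animal without doxycycline, so when these differences arose cannot be told. Of the 19938 genes, 2368 (11.9%) passed a limma adjusted p of 0.05, 1204 of them higher and 1164 lower in the transgenic arrays, and 1779 of these differed by at least 1.5-fold (898 higher, 881 lower). The groups did not overlap for 6826 genes (34.2%, against 10% by chance for 3 against 3). Transgenic replicate 1 stood apart from the other arrays. Its correlation with them across genes was 0.922 to 0.951, against 0.995 to 0.996 between control arrays and 0.996 between transgenic replicates 2 and 3. The first principal component, 66% of the variance, placed it at 79.0, transgenic replicates 2 and 3 at 14.2 and 9.6, and the controls between -35.5 and -31.9. The count of changed genes followed the arrays that entered: it was 5700 without transgenic replicate 1, 1169 without transgenic replicate 2, 683 without control replicate 1, 728 without control replicate 2 and 879 without control replicate 3. All 2368 genes remained called without transgenic replicate 1.

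The genes that rose most were of several kinds. Lcn2, an iron-binding protein of mucosal defence, rose by 5.84 log2 units (SE 0.334, adjusted p = 0.00114), and Lrg1, a secreted acute-phase glycoprotein, rose by 4.22 (SE 0.391, adjusted p = 0.00307). Tat, the tyrosine aminotransferase best known from liver, rose from 5.39 ± 0.07 to 10.55 ± 0.19 (SD, n = 3 each), a difference of 5.15 (SE 0.119, adjusted p = 5.15e-05). The glycosyltransferases B3galt5 and Fut2 rose by 4.20 (SE 0.249) and 4.14 (SE 0.329), and the EGF receptor ligand Ereg rose by 3.75 (SE 0.297). Rasd1 rose by 4.35, the transcription factor Zbtb16 by 3.46, Gml by 4.79 and the ileal bile acid transporter Slc10a2 by 3.49, with adjusted p from 0.0029 to 0.00677. Ly6g rose by 4.87 (adjusted p = 0.0312), tissue factor F3 by 3.80 (0.0108) and the cystine transporter Slc7a11 by 3.55 (0.028). These 3 lost the call when any 1 control was left out, Ly6g and Slc7a11 also without transgenic replicate 2, with adjusted p up to 0.121, 0.0611 and 0.111. Leaving out transgenic replicate 1 kept all 3 calls and gave differences of 3.62 for Ly6g, 3.12 for F3 and 2.68 for Slc7a11, and 5.39 for Gml.

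The genes that fell most were also of several kinds. The cubilin receptor gene Cubn fell by 4.37 log2 units (SE 0.704, adjusted p = 0.0146), the cytochrome P450 gene Cyp2c66 by 3.87 (SE 0.399, adjusted p = 0.00401), and the alcohol dehydrogenase gene Adh4 and the dipeptidase gene Cndp1 differed by -3.17 and -3.10. The nuclear receptor Nr1d1, a part of the circadian clock, fell from 11.14 ± 0.09 to 7.50 ± 0.07 (SD, n = 3 each; SE of the difference 0.0857, adjusted p = 5.15e-05). Olfm4, a marker of crypt base stem cells, fell by 3.37 (SE 0.164, adjusted p = 9.31e-04) and Gstm3, a glutathione transferase, by 3.37 (SE 0.11, adjusted p = 2.24e-04). The MHC class II genes H2-Aa, H2-DMa and H2-Eb1 fell, with differences of -3.72, -3.26 and -3.08. Falls were also found for Cyp3a25 (-3.66, adjusted p = 0.0496), Kcnj13 (-3.26, 0.0417), the nucleoside transporter Slc28a1 (-3.25, 0.0108) and Gsdmc4 (-3.24, 0.0245). The calls of Cubn, Cyp3a25, Kcnj13, Slc28a1 and Gsdmc4 were lost without control replicate 1 or 2. Those of Cubn and Cyp3a25 were also lost without control replicate 3, those of Cyp3a25, Kcnj13 and Gsdmc4 also without transgenic replicate 2 or 3, and their adjusted p reached 0.074, 0.17, 0.16, 0.0605 and 0.107. Leaving out transgenic replicate 1 gave -3.51 for Cubn and -2.58 for Cyp3a25, and leaving out control replicate 3 gave -3.97 for Kcnj13 and -3.96 for Gsdmc4.

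The 40 gene lists fixed beforehand were then compared, by their members first and with the list test camera second. Camera at a preset correlation called 12 lists, 6 in each direction, and none with an estimated correlation (lowest adjusted p = 0.136 with an estimated correlation). Camera also called 10 to 19 lists in the other splits of the 6 arrays into 3 and 3, in which limma called 0 single genes. The median of each list except the Y-linked and X inactivation list is shown for each array in the heat map of list medians.

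**Figure D2:**
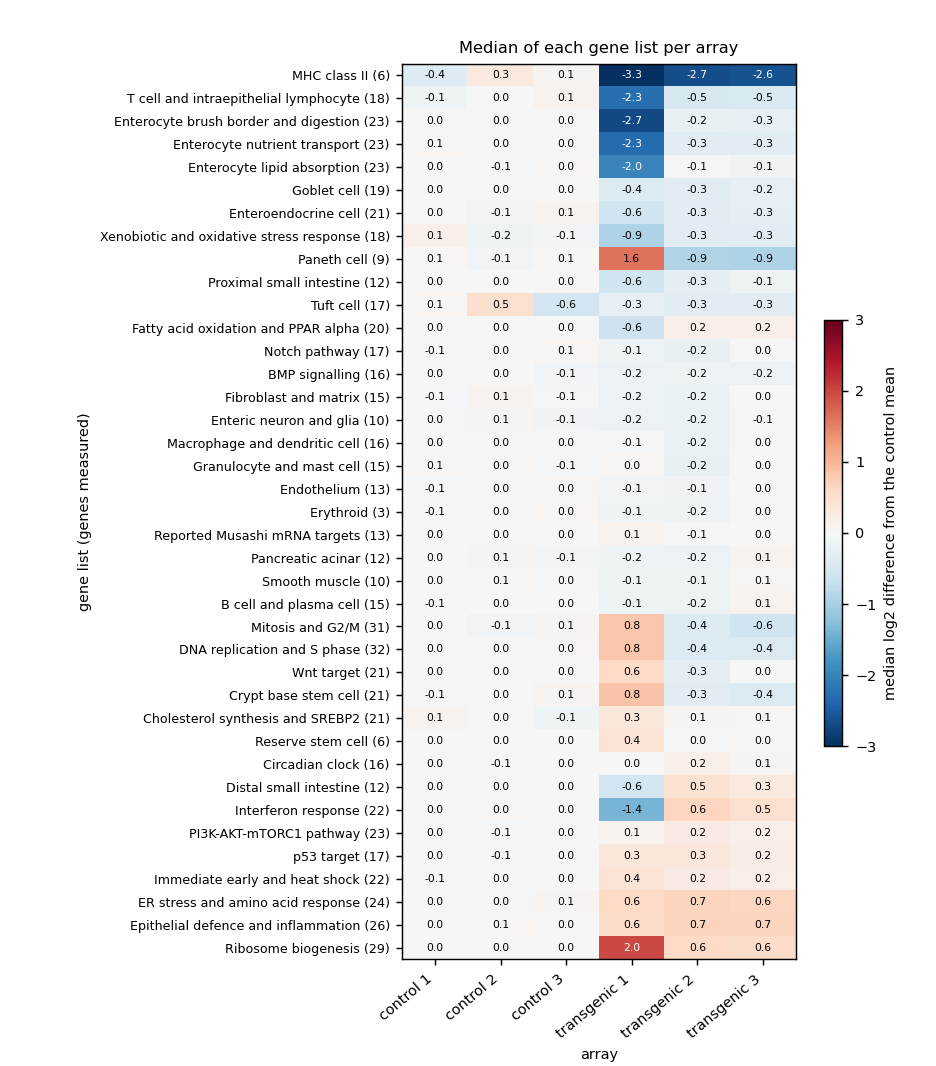
Median over each gene list (rows, number of measured genes in brackets) of the log2 difference from the mean of the 3 control arrays, on each of the 6 arrays (columns), printed in each cell and coloured from blue (lower) to red (higher). The Y-linked and X inactivation list is not shown. MHC class II lay low on all 3 transgenic arrays, while the brush border, Paneth cell, S phase and interferon medians of transgenic replicate 1 lay far from those of transgenic replicates 2 and 3.

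MHC class II genes, which present extracellular antigen, fell as a group. All 6 measured members fell, over all genes and adjusted over the list alone, with a median of -2.91. Cd74, the invariant chain, fell from 11.40 ± 0.33 to 8.78 ± 0.57 (SD, n = 3 each; difference -2.63, SE 0.312, adjusted p = 0.0059), H2-Ab1 differed by -2.73 (adjusted p = 0.0415, and -1.99 without transgenic replicate 1) and Ciita, the master activator of the class, by -0.87 (adjusted p = 0.0166). H2-Ab1 lost its call without any array but transgenic replicate 1 (up to 0.159), and Ciita without control replicate 2 or 3 or transgenic replicate 2 (up to 0.0654). The list test gave an adjusted p of 3.07e-06, and an adjusted p = 0.332 with an estimated correlation. All 6 also passed as lower without transgenic replicate 1 (median -2.63), and 4 or 5 passed with any other array left out. All 6 kept their direction in each of these settings. Of 15 markers of B cells and plasma cells 0 passed, and 1 of 16 macrophage and dendritic cell markers passed, adjusted over each list alone too, namely Cd14, which rose by 1.06 (adjusted p = 0.0119, up to 0.0652 without control replicate 1 or 2). Both lists were near 0 in their medians (-0.04 and -0.10). When transgenic replicate 1 was left out, 0 of the B cell and plasma cell markers passed, while of the macrophage and dendritic cell markers Cd14 and Itgam (0.71) rose and Lyz2 (-1.65), Fcer1g (-0.63) and Tyrobp (-0.50) fell, all but Cd14 named after their values were seen.

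Genes of the unfolded protein response and of the response to amino acid shortage rose. Of 24 measured members 15 rose and 0 fell. Adjusted over the list alone, 21 rose and 1 fell, Edem1 at -0.39, named here after its value was seen. Asns, which makes asparagine, rose by 1.71 (SE 0.12, adjusted p = 0.00158), Ppp1r15a by 1.24 (SE 0.0933, adjusted p = 0.00172), the chaperone Hyou1 by 0.77 (adjusted p = 0.0127) and Pdia4 by 0.67 (adjusted p = 0.0156). Hyou1 lost its call without control replicate 1 or 2 (up to 0.0703), and Pdia4 without these or transgenic replicate 2 (up to 0.0777). A second row of Pdia4 differed by 0.24 and did not pass. The list had a median of 0.66 and a camera adjusted p of 3.58e-11, and an adjusted p = 0.136 with an estimated correlation. It had 20 members higher without transgenic replicate 1 and 2 to 6 with any other array left out.

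Some genes of growth signalling and of ribosome biogenesis rose. Of 23 measured PI3K-AKT-mTORC1 genes 5 rose and 0 fell (7 adjusted over the list alone). They were Eif4ebp1 (1.48, adjusted p = 0.00362), Ddit4 (1.49, 0.00479), Mlst8 (1.04, 0.00659), Rictor (0.76, 0.00902) and Sesn2 (0.70, 0.0316). As background, Ddit4 and Sesn2 restrain the pathway, and Eif4ebp1 restrains its output. Rictor lost its call without control replicate 1 or 2 (up to 0.0548), and Sesn2 without any control or transgenic replicate 2 (up to 0.133). Camera gave an adjusted p of 0.0135, and an adjusted p = 0.774 with an estimated correlation. Without transgenic replicate 1, 9 rose and 3 fell (Pik3cb, Akt1 and Deptor, named after their values were seen), and 3 to 6 rose with any other array left out. Ribosome biogenesis genes had a median of 1.05, and 2 of 29 rose, Ebna1bp2 by 1.12 (adjusted p = 0.0293) and Bysl by 1.34 (adjusted p = 0.0496), with 13 adjusted over the list alone. Both lost the call without any control or transgenic replicate 2, and Bysl also without transgenic replicate 3 (up to 0.125 and 0.184). Nip7 and Ddx21 differed by 1.71 and 1.36 and did not pass, but did so without transgenic replicate 1 (1.18 and 0.93). With camera the list had an adjusted p of 2.48e-09, and an adjusted p = 0.94 with an estimated correlation. The list median was 1.97 above the controls on transgenic replicate 1 and 0.62 on the mean of replicates 2 and 3. Without replicate 1, 23 members passed as higher, and 0 or 1 passed with any other array left out.

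Defence and stress lists also lay higher. Of 26 genes of epithelial defence and inflammation 7 rose and 0 fell: Lcn2, Saa3 (3.32, adjusted p = 0.00184), Ccl20 (1.47, 0.00373), Nfkbia (0.92, 0.00614), Il33 (1.24, 0.00784), Reg3a (1.74, 0.00799) and Nfkbiz (0.60, 0.00963). Il33 lost its call without control replicate 1 (0.0502), and Nfkbiz without control replicate 1 or 2 (up to 0.063). Adjusted over the list alone 10 rose and 1 fell, Reg1 at -2.26, named after its value was seen. Saa2 was 5.79 on transgenic replicate 1 against 9.92 and 9.63 on the other transgenic arrays, and did not pass with all arrays but did without that array (5.18). Camera gave an adjusted p of 9.58e-06, and an adjusted p = 0.158 with an estimated correlation. Of 22 immediate early and heat shock genes 5 rose and 0 fell (6 adjusted over the list alone), among them Egr1 by 2.57 (SE 0.272, adjusted p = 0.0043), Dusp1 by 1.75 (adjusted p = 0.00224), Klf6 by 0.99 (adjusted p = 0.00323) and Atf3 by 1.76 (adjusted p = 0.0186), with Zfp36 the fifth (0.81, 0.0456). Atf3 and Zfp36 kept the call only without transgenic replicate 1 (up to 0.086 and 0.173 with any other array left out). With camera the list had an adjusted p of 3.78e-04, and an adjusted p = 0.158 with an estimated correlation. Of 17 p53 targets 4 rose and 0 fell (8 adjusted over the list alone), namely Sesn2, Pmaip1 (2.27, adjusted p = 0.0408), Phlda3 (0.31, 0.0473) and Trp53inp1 (0.60, 0.0474). Sesn2 lost its call without any control or transgenic replicate 2 (up to 0.133), Pmaip1 and Phlda3 without any array but transgenic replicate 1 (up to 0.159 and 0.205), and Trp53inp1 without control replicate 1 or 2 or transgenic replicate 2 or 3 (up to 0.185). Camera gave the p53 list an adjusted p of 0.00411, and an adjusted p = 0.193 with an estimated correlation. Without transgenic replicate 1 the defence, immediate early and p53 lists had 15, 9 and 8 members higher (and Reg1 lower), with Pmaip1 at 2.89, against 5 to 7, 3 and 0 or 1 with any other array left out.

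Interferon response genes depended on the array. Of 22 measured, 1 rose over all genes and adjusted over the list alone, Mx1 by 2.07 (SE 0.232, adjusted p = 0.00502). The list median was 1.40 below the controls on transgenic replicate 1 and 0.53 above them on the mean of replicates 2 and 3. Rsad2 had 8.03 on transgenic replicate 1, against 11.25 and 11.17 on the other transgenic arrays and 8.13 to 8.60 on the controls. Without transgenic replicate 1, 15 rose and 1 fell (Ddx58, named after its value was seen), and camera gave the list an adjusted p of 2.19e-08 (0.481 with all arrays), and an adjusted p = 0.273 with an estimated correlation (0.967 with all arrays).

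A few genes of enterocytes, the absorptive cells of the villus, passed, and the list medians lay lowest on transgenic replicate 1. Of 23 brush border and digestion genes 2 fell and 0 rose, adjusted over the list alone too: Espn by 1.00 (adjusted p = 0.0136) and Ush1c by 2.01 (adjusted p = 0.0229), both of the microvillus cytoskeleton and its links. Both lost the call without any 1 control (up to 0.0733 and 0.102). The trehalase gene Treh differed by -2.55 and did not pass (adjusted p = 0.168), but fell without transgenic replicate 1 (-1.36, adjusted p = 2e-04). The list median was -2.70 on transgenic replicate 1 and -0.23 on the mean of replicates 2 and 3. Without replicate 1, 11 passed as lower, and 0 to 2 passed with any other array left out. Camera gave an adjusted p of 0.00157, and an adjusted p = 0.94 with an estimated correlation. Of 23 nutrient transporters 2 fell and 0 rose, adjusted over the list alone too: the metal transporter Slc11a2 by 0.68 (SE 0.0801, adjusted p = 0.00571) and Slc28a1, whose call was lost without control replicate 1 or 2 (up to 0.0605). The glucose transporter Slc2a2 differed by -2.73 and did not pass (adjusted p = 0.172), but fell without transgenic replicate 1 (-1.43, adjusted p = 2e-05). With camera the list had an adjusted p of 0.00841, and an adjusted p = 0.94 with an estimated correlation, and without transgenic replicate 1, 12 fell and 4 rose (Slc3a1, Slc28a2, Slc52a3 and Slc34a2, named after their values were seen). Of 23 lipid absorption genes 1 rose, adjusted over the list alone too, the lipid droplet gene Plin2 (0.68, adjusted p = 0.0187, up to 0.0946 without any array but transgenic replicate 1), and 0 fell. The lipid list had a median of -0.65, and camera did not call it (adjusted p = 0.099, and an adjusted p = 0.967 with an estimated correlation). On the 5 arrays other than transgenic replicate 1, 3 rose and 9 fell, with a median of -0.08 and a camera adjusted p of 0.267.

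Secretory cell markers fell in part. Of 19 goblet cell genes 6 fell and 0 rose (7 adjusted over the list alone), with Creb3l4 lower by 1.35 (SE 0.135, adjusted p = 0.00362), Creb3l1 by 0.61 (0.0215), Ccl6 by 1.79 (0.0278) and Capn9 by 1.22 (0.0336). The main goblet mucin Muc2 fell by 0.33 (adjusted p = 0.0363). Creb3l1, Ccl6, Capn9 and Muc2 kept the call only without transgenic replicate 1 (up to 0.1, 0.112, 0.134 and 0.163 with any other array left out). Camera gave an adjusted p of 5.87e-04, and an adjusted p = 0.158 with an estimated correlation. Of 21 enteroendocrine genes 6 fell and 0 rose, adjusted over the list alone too. Gcg, the precursor of the glucagon-like peptides, fell by 1.54 (SE 0.121, adjusted p = 0.00192), Pyy by 0.62 (0.0224), Chgb by 0.70 (0.0257) and Neurog3, which specifies the lineage, by 0.61 (0.0262). Gcg kept its call with each array left out in turn, while Pyy, Chgb and Neurog3 lost it without any 1 control (up to 0.0863, 0.106 and 0.116), Pyy and Neurog3 also without transgenic replicate 2, and Chgb and Neurog3 also without transgenic replicate 3. With camera the list had an adjusted p of 0.00125, and an adjusted p = 0.833 with an estimated correlation. Goblet and enteroendocrine lists each had 10 members lower without transgenic replicate 1, where Neurod1, an enteroendocrine gene named after its value was seen, rose (0.45). With any other array left out, 1 goblet gene and 1 or 2 enteroendocrine genes passed as lower. No Paneth cell gene of 9 and no tuft cell gene of 17 passed, adjusted over the list alone too. Lyz1 was 12.92 on transgenic replicate 1, 11.90 and 11.87 on the other transgenic arrays and 12.67 to 12.89 on the controls. When transgenic replicate 1 was left out, 7 Paneth genes fell and 1 rose (Nupr1, named after its value was seen), and 1 tuft gene fell (Plcg2).

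Most stem cell markers did not pass. Of 21 crypt base stem cell genes 2 fell, Olfm4 and Ascl2 (-1.03, adjusted p = 0.0142), and 1 rose, Rgmb (0.51, adjusted p = 0.0239), with 3 lower and 1 higher adjusted over the list alone. Ascl2 lost its call without control replicate 2 or 3 (up to 0.0733), and Rgmb without control replicate 1 or 2 or transgenic replicate 2 or 3 (up to 0.11). The median was 0.07 (-0.42 without transgenic replicate 1) and the mean -0.16. Lgr5 was 8.56 on transgenic replicate 1, 6.77 and 6.56 on transgenic replicates 2 and 3 and 7.59 to 7.87 on the controls. Without replicate 1, 11 fell and 1 rose (camera adjusted p = 0.00368, against 0.914 with all arrays, and an adjusted p = 0.327 with an estimated correlation, against 0.967). Of 6 reserve stem cell genes Bmi1 rose, by 0.54 (adjusted p = 0.0383, up to 0.142 without any control or transgenic replicate 2), adjusted over the list alone too, and 0 fell. With transgenic replicate 1 left out, Bmi1 rose and Hopx, another marker of the reserve state, fell (-0.80, adjusted p = 3.05e-04), from a difference of -0.48 that did not pass with all arrays. Of 21 Wnt targets 2 fell, adjusted over the list alone too, Ascl2 and Sp5 (-0.65, adjusted p = 0.0286, up to 0.118 without any array but transgenic replicate 1), and 0 rose. With transgenic replicate 1 left out, 7 Wnt targets fell and 1 rose, Myc. Of 17 Notch pathway genes 2 fell, Olfm4 and Lfng (-0.55, adjusted p = 0.0169), and 1 rose, Rbpj (0.46, adjusted p = 0.0408), with 3 lower and 1 higher adjusted over the list alone. Lfng and Rbpj lost the call without any control or transgenic replicate 2 (up to 0.0842 and 0.17). A second row of Rbpj differed by 0.09 and did not pass. On the 5 arrays other than transgenic replicate 1, 5 Notch genes fell and 3 rose. With all arrays the Notch list had an adjusted p of 0.245 with camera and 0.0166 with fry. Of 16 BMP signalling genes 2 rose, adjusted over the list alone too, Id1 (0.70, adjusted p = 0.0162) and Smad1 (0.68, adjusted p = 0.0422), and 0 fell. Id1 lost its call without control replicate 1 or 3 (up to 0.0867), and Smad1 without any array but transgenic replicate 1 (up to 0.165), without which 3 BMP genes rose and 3 fell. Of 13 mRNAs reported elsewhere as Musashi targets 0 passed, adjusted over the list alone too, with Jag1 at 0.62 (adjusted p = 0.148), Itgb1 at 0.29 (adjusted p = 0.148) and Numb at -0.09 (adjusted p = 0.872). Without transgenic replicate 1 Jag1 rose, and Hmga2 and Tspan3 fell, while Numb was at 0.175 and did not pass. The arrays measure RNA only, so a change in the protein made from these mRNAs would not show.

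Proliferation genes showed opposite positions within the transgenic group. The S phase median was 0.83 above the controls on transgenic replicate 1 and 0.44 below them on the mean of replicates 2 and 3, and the mitosis median 0.84 above and 0.46 below. Of 32 S phase genes 1 fell, adjusted over the list alone too, thymidine kinase Tk1 by 1.04 (SE 0.104, adjusted p = 0.00362), and 0 rose. Of 31 mitosis genes Nusap1 rose, by 0.67 (adjusted p = 0.0274, up to 0.123 without any control or transgenic replicate 2), but not when adjusted over the list alone, and 0 fell. Mki67 was 10.33 on transgenic replicate 1, 8.74 and 8.67 on the other transgenic arrays and 9.57 to 9.73 on the controls. With transgenic replicate 1 left out, 22 S phase genes and 20 mitosis genes fell (camera adjusted p = 8.04e-08 and 2.72e-06), against camera adjusted p of 0.881 and 0.86 with all arrays. On those 5 arrays the S phase list had an adjusted p = 0.149 with an estimated correlation and the mitosis list an adjusted p = 0.361 with an estimated correlation (0.967 for both with all arrays), and Nusap1 was higher.

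Circadian clock genes differed in both directions. Of 16 measured, 6 fell and 4 rose (6 and 6 adjusted over the list alone). Nr1d1, Nr1d2 (-1.74, SE 0.144, adjusted p = 0.00222), Tef (-1.04, SE 0.0929, adjusted p = 0.00279), Hlf (-0.88, 0.00541), Dbp (-1.28, 0.00943) and Per3 (-0.81, 0.0095) fell. Nfil3 rose by 2.09 (SE 0.209, adjusted p = 0.00364), Cry1 by 1.75 (0.0043), Ciart by 1.44 (0.0285) and Clock by 0.36 (0.04). Dbp and Per3 lost the call without control replicate 1 or 3 (up to 0.057 and 0.0604), Ciart without any control or transgenic replicate 2 (up to 0.122) and Clock without any array but transgenic replicate 1 (up to 0.158). Arntl, a partner of Clock, differed by 0.55 and did not pass: it was 8.40 on transgenic replicate 1, 9.29 and 9.11 on the other transgenic arrays and 8.27 to 8.45 on the controls. Their median was 0.11 and their mean -0.08, and camera, which tests a shift in 1 direction, gave an adjusted p of 0.91. The list test fry gave an adjusted p of 0.00481. On the 5 arrays other than transgenic replicate 1, 6 rose, Arntl (0.82) and Cry2 (1.93) among them, and 6 fell, and with any other array left out 2 or 3 rose and 4 to 6 fell.

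**Figure D3:**
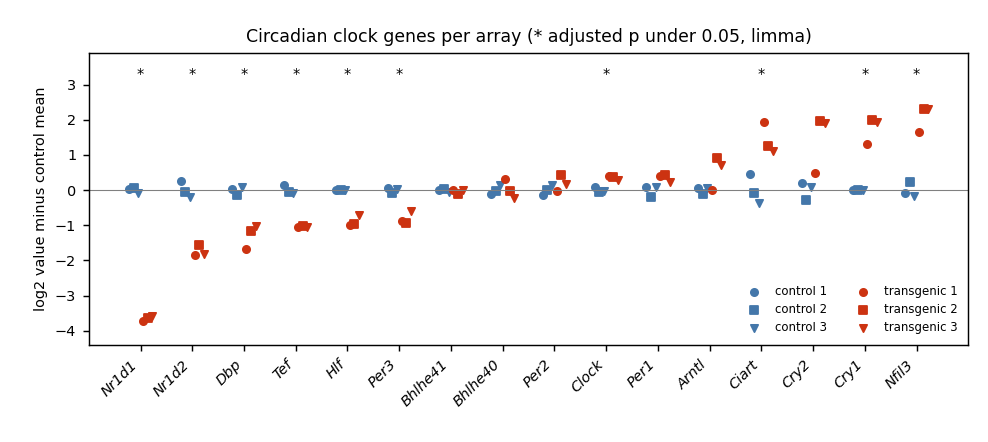
Log2 value minus the mean of the 3 control arrays (vertical axis) for 16 circadian clock genes (horizontal axis), with control arrays in blue and transgenic arrays in red. Nr1d1 differed from the control mean by -3.64 in the transgenic group with little spread, and Nfil3 by 2.09.

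Metabolic genes moved both ways. Of 18 xenobiotic and oxidative stress genes 5 fell and 2 rose (7 and 2 adjusted over the list alone). Gstm3, Cyp2c55 (-3.07, adjusted p = 0.0074), Gstm1 (-1.52, 0.0301), Gclm (-0.59, 0.0319) and Cyp3a25 fell, while Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose by 1.75 (SE 0.122, adjusted p = 0.00158) and Hmox1 by 1.00 (SE 0.109, adjusted p = 0.00468). Cyp3a25 and Gstm1 kept the call only without transgenic replicate 1 (up to 0.17 and 0.111 with any other array left out), and Gclm lost it without any control or transgenic replicate 3 (up to 0.138). When transgenic replicate 1 was left out, 8 fell and 3 rose, and 2 or 3 fell and 2 rose with any other array left out. Of 21 cholesterol synthesis genes 4 rose, Ggps1 (1.17, SE 0.0722, adjusted p = 0.00137), Hsd17b7 (1.11, adjusted p = 0.00268), Fdft1 (0.70, 0.0286) and Lss (1.31, 0.0329), and 3 fell, Tm7sf2 (-1.37, 0.0349), Dhcr7 (-0.52, 0.0405) and Mvk (-0.66, 0.0498), with 6 higher and 4 lower adjusted over the list alone. Fdft1, Lss, Tm7sf2 and Mvk lost the call without any control or transgenic replicate 2, and Fdft1 also without transgenic replicate 3 (up to 0.0983, 0.131, 0.141 and 0.19). Dhcr7 lost it without control replicate 1 or 2 or transgenic replicate 2 or 3 (up to 0.168). With arrays other than transgenic replicate 1 left out, 2 or 3 rose and 0 to 2 fell. Of 20 fatty acid oxidation genes 3 rose, the thioesterases Acot2 (2.16, SE 0.199, adjusted p = 0.00303) and Acot1 (1.88, adjusted p = 0.01) and Acadl (0.94, adjusted p = 0.00409), and 4 fell, Acadm (-0.99, SE 0.124, adjusted p = 0.00671), Ehhadh (-2.02, 0.0322), Hadhb (-0.36, 0.035) and Acadvl (-0.49, 0.0498), adjusted over the list alone too. Acot1 lost its call without any 1 control (up to 0.0582), Ehhadh without these or transgenic replicate 3 (up to 0.132), and Hadhb and Acadvl without any array but transgenic replicate 1 (up to 0.15 and 0.194). With transgenic replicate 1 left out, 7 rose and 4 fell, and with any other array left out 2 or 3 rose and 1 or 2 fell. The median of the fatty acid list was -0.24 with all arrays and 0.13 without transgenic replicate 1, and its mean with all arrays 0.00.

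Genes used to tell parts of the small intestine apart passed in small numbers and in both directions. Of 12 distal genes 2 rose, Slc10a2 and the bile acid receptor Nr1h4 (1.42, SE 0.114, adjusted p = 0.00196), and 2 fell, Cubn and Pyy (3 and 2 adjusted over the list alone). Cubn lost its call without any 1 control (up to 0.074) and Pyy without these or transgenic replicate 2 (up to 0.0863). The distal list had a median of 0.12, or 0.38 without transgenic replicate 1, and a mean of -0.27. Of 12 proximal genes 0 passed, adjusted over the list alone too. On the 5 arrays other than transgenic replicate 1, 5 distal genes rose and 4 fell, and 5 proximal genes fell (Cybrd1, Fabp1, Lct, Gip and Adh6a, named after their values were seen).

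Among markers of other cells, those of T cells and intraepithelial lymphocytes lay lower. Of 18 measured 2 fell and 0 rose, adjusted over the list alone too: Cd8b1 by 0.55 (SE 0.0792, adjusted p = 0.0101) and Xcl1 by 0.55 (adjusted p = 0.016). Both lost the call without any 1 control, and Xcl1 also without transgenic replicate 2 (up to 0.0686 and 0.0805). The list median was -2.27 on transgenic replicate 1 and -0.48 on the mean of replicates 2 and 3, and Nkg7 was 5.52, 8.19 and 8.17 on transgenic replicates 1 to 3 and 8.87 to 9.22 on the controls. Camera gave an adjusted p of 0.00131, and an adjusted p = 0.94 with an estimated correlation. When transgenic replicate 1 was left out, 11 fell. Of 15 granulocyte and mast cell genes Ly6g alone passed, while S100a8 differed by 0.01. Vim fell by 0.89 among 15 fibroblast genes (adjusted p = 0.0227, up to 0.101 without any control or transgenic replicate 2), Mylk by 0.56 among 10 smooth muscle genes (0.0115, up to 0.0732 without control replicate 1 or 3) and Snap25 by 0.62 among 10 neuron and glia genes (0.0473, up to 0.184 without control replicate 1 or 3 or transgenic replicate 2 or 3). Lyve1 rose by 1.60 among 13 endothelial genes (SE 0.203, adjusted p = 0.00692). These counts were the same adjusted over each list alone, except that Snap25 no longer passed. Of 3 erythroid and 12 pancreatic acinar genes 0 passed, adjusted over each list alone too. On the 5 arrays other than transgenic replicate 1 these single calls were kept, and further genes fell: Mcpt1, Mcpt2 and Kit of the granulocyte and mast cell list (-1.08, -1.11 and -1.02), Dcn (-0.59), Smtn (-0.48) and Esam (-0.59). Clps, of the pancreatic acinar list, fell there too (-2.28), and these genes were named after their values were seen. Clps was 12.47 on transgenic replicate 1, 9.14 and 9.16 on the other transgenic arrays and 11.22 to 11.67 on the controls. Cpa1 and Cpb1 of that list had control means of 5.82 and 4.47, so the fall of Clps is not read as a change in pancreatic tissue.

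The arrays also differed in sex-linked genes. Control replicate 1 alone carried Y-linked signal, with Kdm5d at 7.13, Eif2s3y at 9.17 and Uty at 8.63, and had a low Xist signal of 5.32. On transgenic replicates 1 to 3 Eif2s3y was 3.33, 3.36 and 3.42, and Xist was 11.54, 11.38 and 11.25. On control replicates 2 and 3 Eif2s3y was 3.24 and 3.30, and Xist was 11.28 and 11.39. These signals are those of a male for control replicate 1 and of females for the other arrays, while the labels used here give no sex. Sex was thus not balanced between the groups and was not a term in the test. None of the 4 genes passed between the groups, adjusted over the list alone too. Without both control replicate 1 and transgenic replicate 1, a setting added after the data were seen, 4573 genes were called, of which 2290 were among the 2368.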

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

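The tests of transgenic replicate 1, of the MHC class II genes and of the clock genes were chosen after those results were seen, and the splits of the arrays were planned. Signal outside the main measurement was found in rows that were not named: 38 of 1621 rows with several gene symbols and 210 of 11989 rows with no symbol were higher in the transgenic arrays at a limma adjusted p under 0.05 over all rows, and 30 and 93 were lower.

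Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many as 2368 genes, and the highest other count was 0. For genes changed at least 1.5-fold the real count was 1779, reached by 1 split, and the highest other 0. For gene lists, 9 of the 10 splits gave at least the real 12, and the highest other was 19, so the number of lists called does not set the real grouping apart. With 10 splits no share under 0.05 can be reached.

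Transgenic replicate 1 stood apart from the other transgenic arrays. An animal without the transgene is argued against, since its Msi1 signal differed from the mean of replicates 2 and 3 by -0.14. A larger response of the same kind is argued against for the S phase, mitosis and Paneth lists, since all 3 medians lay on opposite sides of the controls in replicate 1 and in replicates 2 and 3. Over the 40 lists 6 medians lay over 0.3 from the controls on opposite sides. On the same side 7, such as ribosome biogenesis (1.97 against 0.62) and T cells (-2.27 against -0.48), lay further out in replicate 1, and 2 lay nearer. Among the 7 is the Y-linked and X inactivation list (-1.42 against -1.35), with control replicates 2 and 3 at -1.29 and -1.30. Its offset comes from control replicate 1 (2.59) and cannot be a larger response. For the others of the 7 a larger response stays open. A candidate explanation is a preparation with fewer villus and more crypt cells. The brush border median of replicate 1 was -2.51 relative to the mean of replicates 2 and 3, with S phase at 1.21 and Paneth cells at 2.55. Of 21 crypt base stem cell genes 19 lay higher and 2 lower. These lists were picked after their values were seen and cannot test the explanation. Fibroblast and endothelial medians were -0.07 and -0.03. Some of their markers had control means under the median of all genes, 6.64, with little room to fall, such as Pdgfrb (6.46), Sparc (6.16) and Cdh5 (5.57). Vim (8.59) and Dcn (6.84) lay above it. An effect of the transgene that differed between animals was not tested and stays open.

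MHC class II genes were lower on all 3 transgenic arrays. The preparation of transgenic replicate 1 is argued against as the whole cause, since the median without it was -2.63. A different H2 haplotype under the probes is argued against as the whole cause by Cd74 and Ciita, which lie on other chromosomes (18 and 16) and fell by at least 5.9 SE (Ciita with an adjusted p up to 0.0654 with 1 array left out), but a part of the fall of the H2 genes stays open. Fewer B cells, macrophages and dendritic cells cannot be told apart from lower expression in the epithelium. The 31 markers of these cells had a median difference of -0.06 (3 fell and 2 rose without transgenic replicate 1). Their control median of 5.71 lay under that of all genes, 6.64, which left little room to fall. Class II genes had a control median of 10.77, against 5.66 for the B cell list and 5.72 for the macrophage list. Which cells gave the class II signal was not tested. An effect of Msi1 may account for the rest, as a hypothesis that the design does not separate from other differences between the animals.

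Clock genes differed between the groups in both directions. The preparation of transgenic replicate 1 is argued against, since 12 clock genes passed without it. A candidate explanation is a different clock phase or hour of collection. Genes placed in phase with Nr1d1 and Dbp had a median of -0.88 and those placed in the opposite phase 1.15, a gap of 2.03. These sets were written after the values were seen, so the gap restates the falls and rises and cannot test the explanation. Of the 9 genes placed in phase with Nr1d1, 3 did not fall. Ciart rose by 1.44 (adjusted p up to 0.122 with 1 array left out), and Per1 and Per2 differed by 0.36 and 0.19 and did not pass. Arntl, placed in the opposite phase, differed by 0.55, did not pass and lay at the control level on transgenic replicate 1 (8.40). Other clock genes, Cry2 among them, were placed in neither set. An effect of Msi1 on the clock was not tested and stays open, since the labels used here give no hour of collection.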

How the results depend on the processing

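All 2368 genes kept their direction under every alternative in which they were tested. The groups did not overlap for any of the 2368, so leaving out or weighting arrays, blocks and moderation could not have reversed a direction. Only quantile normalization, equal array medians and the mean of a gene's rows could have done so. Calls depended on the arrays that entered: leaving out each array in turn gave 683 to 5700 genes (359 to 2800 higher, 324 to 2900 lower, 681 to 2782 changed at least 1.5-fold), and a set of 4 or 5 arrays gives other degrees of freedom. Array weights, which gave transgenic replicate 1 a weight of 0.12, called 5770 genes (2846 higher, 2924 lower, 2893 at least 1.5-fold), and without both transgenic replicate 1 and control replicate 1, added after the data were seen, 4573 passed (2317, 2256 and 2766). The replicate block on title numbers gave 733 genes (384 higher, 349 lower, 733 at least 1.5-fold), and the block on description numbers 4019 (2056, 1963 and 2828). Deviations of same-numbered arrays from their group means correlated at -0.07, -0.168 and -0.122. Transgenic replicate 1 stands apart and so shapes the deviations of its whole group, and the check cannot decide whether the numbers pair animals. Neither block is read as a weaker or stronger effect. Quantile normalization, equal array medians (58.6% of calls higher, against 50.8%), removal of dim genes, trend and robust moderation, and the mean of a gene's rows gave 1976 to 2372 genes.

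The Msi2 difference passed with the description block (-0.62, a fit with 1 residual degree of freedom), array weights (-0.53, 0.00238) and without both doubted arrays (-0.62, 0.00456), and leaving out each array gave -0.60 to -0.32. Its adjusted p over all these settings ran from 0.0011 to 0.412, and the cause was not tested. Msi1 passed in every setting. The count of 12 lists was 21 with the description block and 0 with an estimated correlation (also 0 with it and without transgenic replicate 1, added after the data were seen), 9 with fry, and 11 to 18 elsewhere. Fry kept 7 of the 12 and lost 5. Those lost were ribosome biogenesis (fry adjusted p = 0.194), brush border (0.389), nutrient transport (0.343), enteroendocrine (0.0582) and T cells (0.212). It also called the Notch (0.0166) and clock (0.00481) lists, which camera did not call. Of the 94 genes that passed among the largest differences and the up to 4 members chosen per list, 49 kept the call with each array left out and 55 under the replicate block, and of all 147 members of the lists, fixed or added, that passed, 58 kept it with each array left out. Among the largest differences and the up to 4 members chosen per list, signs reversed for 5 genes, none of which passed in either setting. They were Epb42 (-0.016 with array weights), Slc4a1 (0.013 with quantile normalization, -0.178 to 0.009 with 1 array left out), Cnn1 (-0.009 to 0.218 with 1 array left out), Xist (-0.02 with the description block and without both doubted arrays, 0.053 to 3.089 with 1 array left out) and Eif2s3y (0.12 and 0.12, and -2.87 to 0.10 with 1 array left out). For Xist and Eif2s3y these settings remove the weight of control replicate 1, the array with Y-linked signal. The count leaves out genes named outside that set, such as Numb. Numb was -0.09 with all arrays and 0.175 without transgenic replicate 1, and passed in neither. Genes near the lower end of the signal scale have the least room to show a fall.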

Other observations

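The glucocorticoid test was planned before its second list was seen, and the gene families were chosen after the named genes were seen. Of 19 glutathione transferase genes, a family chosen because Gstm3 and Gstm1 had been seen to fall, 10 fell, 0 rose and 9 did not pass (12 fell and Gsta4 rose without transgenic replicate 1). The other falls included Gstm4 by 1.88 (limma adjusted p = 0.00224), Gstm7 by 1.75 (0.00501) and Gstt2 by 0.84 (0.00677). Gstm3, Gstm4, Gstm7, Gstt2 and Gstz1 kept the call with each array left out. Gstm1, Gstm2, Gstm6, Gstp1 and Gstt1 lost it without any 1 control (up to 0.172). Of 86 cytochrome P450 genes 11 fell and 0 rose, among them Cyp2s1 (-3.06, adjusted p = 0.00274) and Cyp4f40 (-1.80, 0.00191). Cyp2s1, Cyp4f40, Cyp2c55 and Cyp2c66 kept the call with each array left out, and the other falls lost it at least once (up to 0.17). Cyp4a12a and Cyp4a12b differed by 4.35 and 3.86 and did not pass (adjusted p = 0.0766 and 0.0722). Without transgenic replicate 1, 8 P450 genes rose, Cyp4a12a (5.85) and Cyp4a12b (5.16) among them, and 19 fell. Of 15 Slc7 amino acid transporter genes 3 rose and 0 fell, Slc7a11, Slc7a5 by 2.74 (adjusted p = 0.0053) and Slc7a1 by 1.32 (0.0286, up to 0.117 with 1 array left out), and without transgenic replicate 1, 6 rose and 3 fell. Of 8 ligands of the EGF receptor family Ereg, Btc (1.91, adjusted p = 0.0319) and Hbegf (1.52, 0.0211) rose (up to 0.135 and 0.0939 with 1 array left out), and Nrg4 fell by 0.86 (0.00307). Of 11 Hsd17b genes 2 rose and 1 fell, and of 4 Gsdmc genes 1 fell, against 2 higher and 4 lower and 2 lower without transgenic replicate 1.

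Tat, Zbtb16, Rasd1 and Fkbp5 are known to respond to glucocorticoids, and a hypothesis was that the transgenic animals had a higher glucocorticoid level. The 14 such genes whose values had been seen had a median of 1.45 with 8 higher, which cannot test the hypothesis that they raised. A second list of 15 responsive genes, written before their values were seen, had a median of 0.02, with Tgm2 higher (0.94, adjusted p up to 0.13 with 1 array left out) and Usp2 lower (-2.19), and a camera p of 0.71. Without transgenic replicate 1, 3 of the 15 were higher, Rhob (0.95), Tgm2 (0.74) and Map3k6 (0.63), and Usp2 was lower, with a median of -0.04 and a camera p of 0.431. The second list thus showed no shift as a whole by camera, while single members went both ways.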
